A study of Mus musculus with 24 samples.

How the data were processed

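Poly(A)-enriched mRNA of wild-type mouse primary chondrocytes was sequenced in 24 libraries, 3 for each of 8 groups formed by culture (normal or with dermal fibroblasts), IL-1β (none or 10 ng/ml) and time (36 h or 72 h). Per the labels, chondrocytes were cultured in DMEM/F12 with ITS and 10% FBS and dermal fibroblasts in alpha-MEM with 10% FBS. The medium of the co-cultures was not given in the sources used here, so a difference in medium between co-culture and normal culture remains possible. The fibroblasts were not sequenced in these libraries.

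The deposited table held 1 FPKM value per gene and library, rounded to 2 decimals, which the authors had computed per kilobase of gene and per 1000000 mapped fragments on genome build GRCm38. The aligner, the counting tool, the annotation and any filter were not given in the sources used here. The table had 17094 rows, 1 per NCBI gene, of which 3 were 0 in every library and 528 had no Ensembl ID. Read counts were not analysed here. The depth could not be recovered from the values: among 592 low values of 62 genes, 12.7% lay within 0.05 of a whole multiple of the smallest step, where chance gives 10%, so no counting interval is given. Of 16561 distinct Ensembl IDs in the table, 16539 were found in GENCODE vM21, which supplied the gene positions.

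Genes with an FPKM of at least 1 in at least 3 libraries were tested, 12178 in all. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 with a trended prior, as 1 mean per group over all 24 libraries, leaving 16 residual degrees of freedom. The comparisons were IL-1β against none in each culture and time, co-culture against normal culture with and without IL-1β at each time, the interaction of both at each time, the differences of the IL-1β effect in normal culture and of the co-culture effect under IL-1β between 72 h and 36 h, and 72 h against 36 h in untreated normal culture. A gene passed at an adjusted p under 0.05 (Benjamini-Hochberg over the tested genes of a comparison), and counts at a fold of at least 2 are on the scale of log2(FPKM + 1), which compresses the change of genes near 0. Figures were drawn with matplotlib 3.10.9 under Python 3.11. The draws of simulated values used seed 1, and those of random gene lists seed 2.

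Of 33 gene lists with 609 genes and 637 entries, 26 genes were missing from the table, including all 13 mitochondrially encoded genes, which left 32 lists to test. Each was tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Genes past the threshold were also counted after adjustment over the list alone. The genes raised or lowered at least 2-fold by IL-1β at one time were tested in the co-culture effect under IL-1β and in the interaction at the other time, so that list and comparison shared no library.

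The genes eligible to be named were 13 core genes whatever their result, up to 6 higher and 6 lower genes with the largest change among those past the threshold with no overlap between the compared libraries (a condition dropped for interactions and differences between times) and a mean of at least 5 FPKM in the higher group, up to 4 changed members of each described list, and up to 3 most expressed members of lists of other cell types. Genes without a usual symbol were left out. The text prints a selection of the eligible genes. The lists, this rule, the tests and the main alternatives were chosen before the data were examined. Those alternatives were log2(FPKM + 0.1), no filter (17091 genes), a filter at 5 FPKM (9346 genes), rescaling to TPM, median-of-ratios scaling, fitting the compared groups only, the replicate number as a block over all libraries or within each time, and leaving out each library in turn. Alternatives added after the data were seen were weights per library, weights per group, the compared groups only with the replicate block, list counts without single libraries, a list of immediate early genes, and the medians of single lists under each scaling. Same-numbered libraries of a comparison counted as deviating together where the correlation was above 0.1 for each number. That held for the co-culture effect under IL-1β at 72 h alone (0.364, 0.179 and 0.577). The main fit had no replicate block even there, so its calls and p-values took no account of pairing. The block entered alternative fits only.

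The procedure was tested on simulated data built from these libraries, with the comparison of IL-1β at 36 h in normal culture. Of 200 genes given a known change in each of 5 draws, 57.2% were recovered at 1.25-fold, 89.6% at 1.5-fold, 98.4% at 2-fold and 98.8% at 4-fold. Of the calls, 5.59% were false, and a comparison left unchanged gave 0 limma calls per draw. Random gene lists had an unadjusted p under 0.05 in 3.5% of cases with camera and 3% with fry. The draws gave every group the same spread and left the genes uncorrelated. They therefore could not show false calls that come from unequal spread between groups or from correlated genes.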

Results

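RNA sequencing was performed on mouse primary chondrocytes, the cells that make and maintain cartilage matrix. The cells grew in the lower chamber of transwell plates, whose porous insert lets secreted factors pass while keeping 2 cell populations apart. They were kept alone (normal culture) or with primary dermal fibroblasts (co-culture), and either left untreated or given IL-1β at 10 ng/ml from 24 h after attachment. IL-1β is an inflammatory cytokine widely used in culture to produce changes like those of osteoarthritic cartilage. Chondrocytes were collected 36 h and 72 h after the addition of IL-1β, which gave 8 groups of 3 libraries, 24 in all. Each library was given as FPKM for 17094 genes, with sums between 438242 and 506621 FPKM and between 11335 and 11607 genes at 1 FPKM or more. The number of reads behind these values is unknown, so no counting interval can be given. Below, levels are the mean ± SD in FPKM (SD, n = 3), and changes are differences of log2(FPKM + 1) tested with limma and Benjamini-Hochberg adjustment over 12178 genes. Nothing in the labels states that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

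Libraries of one group resembled each other closely, with Pearson correlations across genes of 0.989 to 0.998. The first principal component held 53.9% of the variance and separated IL-1β-treated from untreated cultures, and the second held 29.1% and separated 36 h from 72 h. The IL-1β-treated groups at 72 h were the most variable, with a residual SD of 0.167 on the log2 scale in normal culture and 0.119 in co-culture, against 0.0853 to 0.0994 in the other 6 groups.

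**Figure D1:**
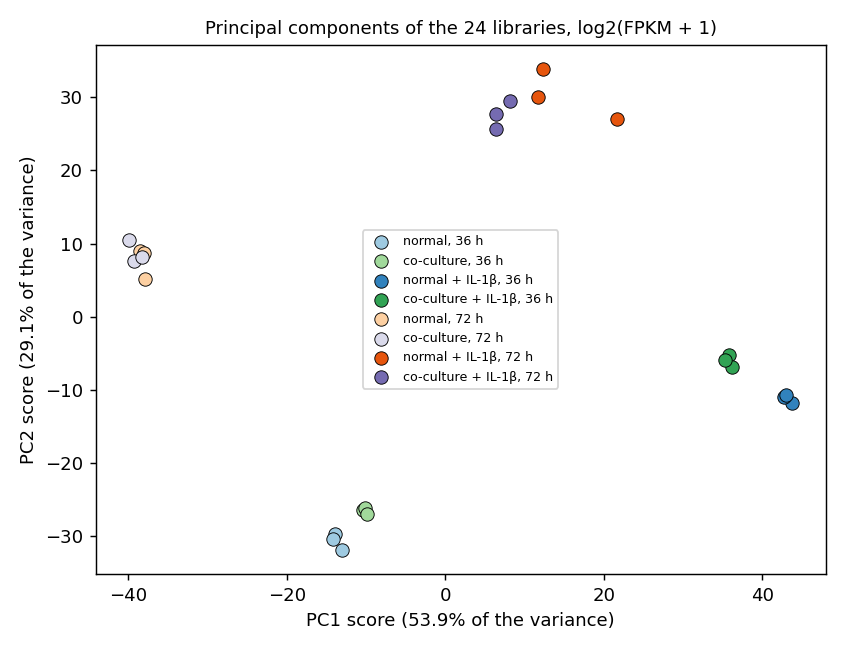
Scores of the 24 libraries on the first 2 principal components of log2(FPKM + 1), each point 1 library, coloured by group, with axes giving the score and the share of variance (53.9% and 29.1%). IL-1β-treated and untreated libraries of the same time lie apart along the first axis, and 36 h and 72 h libraries along the second, while co-culture and normal culture lie close together within each pair.

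Among the principal genes, Col2a1 (ENSMUSG00000022483) lies on chromosome 15 at 97975602 to 98004695 on the minus strand of GRCm38. Acan (ENSMUSG00000030607) lies on chromosome 7 at 79053483 to 79115099 on the plus strand, and Sox9 (ENSMUSG00000000567) on chromosome 11 at 112782224 to 112787760 on the plus strand. The matrix protease genes Mmp3 (ENSMUSG00000043613, 7445822 to 7455975) and Mmp13 (ENSMUSG00000050578, 7272514 to 7283331) both lie on the plus strand of chromosome 9. Il6 (ENSMUSG00000025746) lies on chromosome 5 at 30013114 to 30019981, Nos2 (ENSMUSG00000020826) on chromosome 11 at 78920787 to 78960254, and Ptgs2 (ENSMUSG00000032487) on chromosome 1 at 150100031 to 150108227, all on the plus strand. Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) and Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860) are on the minus strand. Car9 (ENSMUSG00000028463, chromosome 4, 43506966 to 43513729), Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) and Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) are on the plus strand. All 14 are protein-coding genes, and the positions span the whole gene.

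The first comparison asked what IL-1β did to chondrocytes in normal culture at 36 h. Inflammatory genes rose steeply: Saa3, an acute phase serum amyloid, rose from 108 ± 9.68 to 8778 ± 116 FPKM and Il6 from 40.8 ± 2.99 to 621 ± 87.4. Nos2, the inducible nitric oxide synthase, rose from 1.34 ± 0.052 to 95.3 ± 6.61. Ptgs2, which encodes cyclooxygenase 2, rose by 4.69 on the log2 scale, the chemokine genes Ccl5 and Cxcl2 by 6.25 and 4.99, and the cytokine gene Lif by 4.55. Cartilage genes fell: Col2a1, the main collagen of cartilage, fell from 302 ± 11.7 to 117 ± 3.83 FPKM, and Acan, the core protein of aggrecan, from 9.85 ± 0.375 to 1.18 ± 0.155. Sox9, the transcription factor that drives both, fell from 30.3 ± 0.896 to 6.4 ± 0.271. Mmp3, which encodes stromelysin 1, rose from 186 ± 24.8 to 2803 ± 93.5 FPKM. These changes had standard errors of 0.05 to 0.22 on the log2 scale (limma, adjusted p = 2.83e-13 or lower).

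By list, 17 of 20 tested inflammatory cytokine and chemokine genes rose and 2 fell at 36 h (median 2.28, camera adjusted p = 2.99e-12, adjusted p = 0.0469 with an estimated correlation), where the median is that of the log2 changes of the list. Il1rn, the IL-1 receptor antagonist and not a member of this list, fell by 3.11. Of the NF-kB targets and feedback genes, 14 of 19 rose and 2 fell (median 0.71, camera adjusted p = 1.82e-07, adjusted p = 0.00498 with an estimated correlation). Zc3h12a, an RNase that degrades cytokine transcripts, rose by 2.34 and Nfkbia, the inhibitor of NF-kB, by 1.86. 9 of 11 acute phase, prostaglandin and nitric oxide genes rose and 2 fell (median 2.03, camera adjusted p = 2.56e-06, adjusted p = 0.0737 with an estimated correlation). Lcn2, a siderophore-binding lipocalin, rose from 175 ± 14.3 to 3166 ± 139.8 FPKM. In cartilage matrix, 17 of 21 genes fell and 3 rose (median -1.02, camera adjusted p = 0.000322, adjusted p = 0.39 with an estimated correlation). Comp fell by 3.05 on the log2 scale and Cnmd, the chondrocyte glycoprotein chondromodulin, by 3.65. Matrix-degrading enzymes were mixed, with 16 of 28 higher and 6 lower (median 0.22, camera adjusted p = 0.00219, adjusted p = 0.0201 with an estimated correlation). Mmp9 rose by 3.39, Mmp13, a collagenase that cleaves type II collagen, by 0.78 and Adamts4, an aggrecanase, by 0.44, while the other aggrecanase gene Adamts5 stood at 52.8 ± 3.27 against 50.7 ± 2.12 FPKM (adjusted p = 0.474). Each of these counts was the same when adjusted over the list alone.

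Genes outside inflammation and cartilage also moved at 36 h. All 34 tested cell cycle genes fell (median -1.51, camera adjusted p = 2.48e-12, adjusted p = 0.351 with an estimated correlation). Mcm3 fell by 2.26 and Tk1 by 2.32, while Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 99.8 ± 7.84 to 466 ± 2.69 FPKM. Of the p53 target and senescence genes, 14 of 19 rose and 4 fell (median 1.10, camera adjusted p = 2.56e-06, adjusted p = 0.10 with an estimated correlation). 17 of 20 NRF2 and antioxidant genes rose (median 1.20, camera adjusted p = 8.60e-12, adjusted p = 0.0201 with an estimated correlation). Nqo1, a quinone reductase, rose by 3.40 and Hmox1, heme oxygenase 1, by 1.77. Myofibroblast and actin cytoskeleton genes rose in 14 of 15 cases (median 0.82, camera adjusted p = 1.82e-07, adjusted p = 0.135 with an estimated correlation), with Cnn1 at 1.63. TGF-beta and BMP response genes rose in 13 of 21 with 4 lower (median 0.56, camera adjusted p = 0.000469, adjusted p = 0.0462 with an estimated correlation), with the activin subunit gene Inhba at 2.87. The unfolded protein and amino acid stress genes fell in 16 of 24 cases and rose in 3 (median -0.40, camera adjusted p = 0.00867, adjusted p = 0.415 with an estimated correlation), with Trib3 lower by 2.80. Among the steepest falls outside these lists were those of Msmp (from 46.7 ± 4.57 to 0.337 ± 0.326 FPKM) and the imprinted gene Mest (from 1164 ± 29.6 to 45.3 ± 3.41). The ferritin receptor gene Scara5 fell from 20.1 ± 1.04 to 0.51 ± 0.0265, Ecrg4 from 133 ± 11.4 to 9.1 ± 1.3 and the WNT modulator gene Sfrp2 from 276 ± 9.91 to 20.3 ± 1.23. Prg4, which encodes the joint lubricant lubricin, rose by 1.87, Col1a1 fell by 0.62 and Col10a1, a marker of hypertrophy, rose by 0.37 (adjusted p = 0.0234). In all, 8215 of 12178 genes passed the threshold, 3159 higher and 5056 lower, and 461 and 478 of these changed at least 2-fold. The balance of higher and lower depended on scaling: 2631 rose and 5715 fell after rescaling to TPM, and 3864 and 4172 after median-of-ratios scaling. TPM moved the median of all genes from -0.0857 to -0.149 here, to -0.203 for IL-1β at 72 h, and to -0.131 and -0.151 for IL-1β in co-culture at 36 h and 72 h, against which small changes have to be read.

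At 72 h the same comparison in normal culture gave larger differences for many inflammatory genes. Saa3 stood at 7439 ± 887 against 4.62 ± 2.35 FPKM in IL-1β-treated and untreated cells, and Lcn2 at 2291 ± 285 against 2.58 ± 0.427. Il6 stood at 687 ± 61.3 against 4.29 ± 0.652, Mmp3 at 1440.4 ± 371 against 2.55 ± 0.911 and Mmp13 at 348 ± 96.7 against 10.3 ± 1.34. Nos2 rose by 7.31 on the log2 scale, Ccl2, which attracts monocytes, by 5.26, Cxcl2 by 6.01 and C3, the central complement component, by 5.54. Col2a1 fell from 765 ± 3.38 to 200.01 ± 10.9 FPKM, Acan from 18.6 ± 1.03 to 1.48 ± 0.642 and Sox9 from 26.4 ± 1.91 to 7.98 ± 1.91. The matrix genes Ogn (from 247 ± 24.5 to 22.2 ± 6.39 FPKM), Omd, Ccn3 and Eln fell by 3.45, 3.33, 3.19 and 3.00 on the log2 scale. Comp fell by 2.70 and Mest by 4.29 (limma, adjusted p = 4.07e-13 or lower for every gene named so far at 72 h).

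The lists at 72 h showed 19 of 20 inflammatory genes higher (median 3.71, camera adjusted p = 1.20e-17, adjusted p = 0.0205 with an estimated correlation). Of the NF-kB genes 17 of 19 were higher (median 1.14, camera adjusted p = 1.39e-15, adjusted p = 5.55e-05 with an estimated correlation), with Zc3h12a at 3.69. All 11 acute phase, prostaglandin and nitric oxide genes were higher (median 3.02, camera adjusted p = 2.80e-14, adjusted p = 0.00792 with an estimated correlation). Complement genes rose in 7 of 10 cases (median 0.91, camera adjusted p = 0.000232, adjusted p = 0.0569 with an estimated correlation). Hypoxia and glycolysis genes rose in 29 of 31 (median 1.08, camera adjusted p = 1.02e-20, adjusted p = 0.0569 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase that hypoxia induces, rose from 3.27 ± 0.528 to 42.1 ± 6.44 FPKM, and the glucose transporter gene Slc2a1 by 1.70. NRF2 and antioxidant genes rose in 16 of 20 (median 0.66, camera adjusted p = 2.56e-10, adjusted p = 0.0205 with an estimated correlation), and the metallothionein gene Mt2 by 3.48. Cartilage matrix genes fell in 18 of 21 cases (median -1.19, camera adjusted p = 3.85e-06, adjusted p = 0.158 with an estimated correlation). Cell cycle genes fell in 33 of 34 (median -0.71, camera adjusted p = 2.67e-07, adjusted p = 0.351 with an estimated correlation), with Kif11 lower by 1.21. Cholesterol synthesis genes fell in 20 of 23 (median -0.39, camera adjusted p = 0.000178, adjusted p = 0.158 with an estimated correlation) with Hmgcs1 lower by 0.84. After adjustment over the list alone, 21 cholesterol genes and 2 complement genes were lower, against 20 and 1 over all genes, and the other counts in this paragraph did not differ. In the same comparison all 12 skeletal muscle markers were higher (median 0.82, camera adjusted p = 6.57e-06, adjusted p = 0.16 with an estimated correlation). Examples were 28.8 ± 2.01 against 14.7 ± 0.796 FPKM for Acta1 and 5.91 ± 0.679 against 2.35 ± 0.146 for Des. The neutrophil and myeloid gene S100a8 also rose, from 0.503 ± 0.521 to 19.9 ± 3.02.

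Of the other core genes at 72 h, Ptgs2 rose by 3.59 and Prg4 by 1.01, Adamts4 rose by 0.66 while Adamts5 fell by 0.51, Col1a1 fell by 0.27 and Col10a1 fell by 0.96 (adjusted p = 0.000199 or lower). Of 12178 genes, 7718 passed the threshold, 2809 higher and 4909 lower, with 401 and 237 changed at least 2-fold. The split was 2005 higher and 6508 lower after TPM rescaling and 3567 and 3957 after median-of-ratios scaling. At 36 h and 72 h together, 1820 genes were higher at both times (729 would be shared by independent lists), 3301 were lower at both (2038), and 645 passed in opposite directions.

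**Figure D2:**
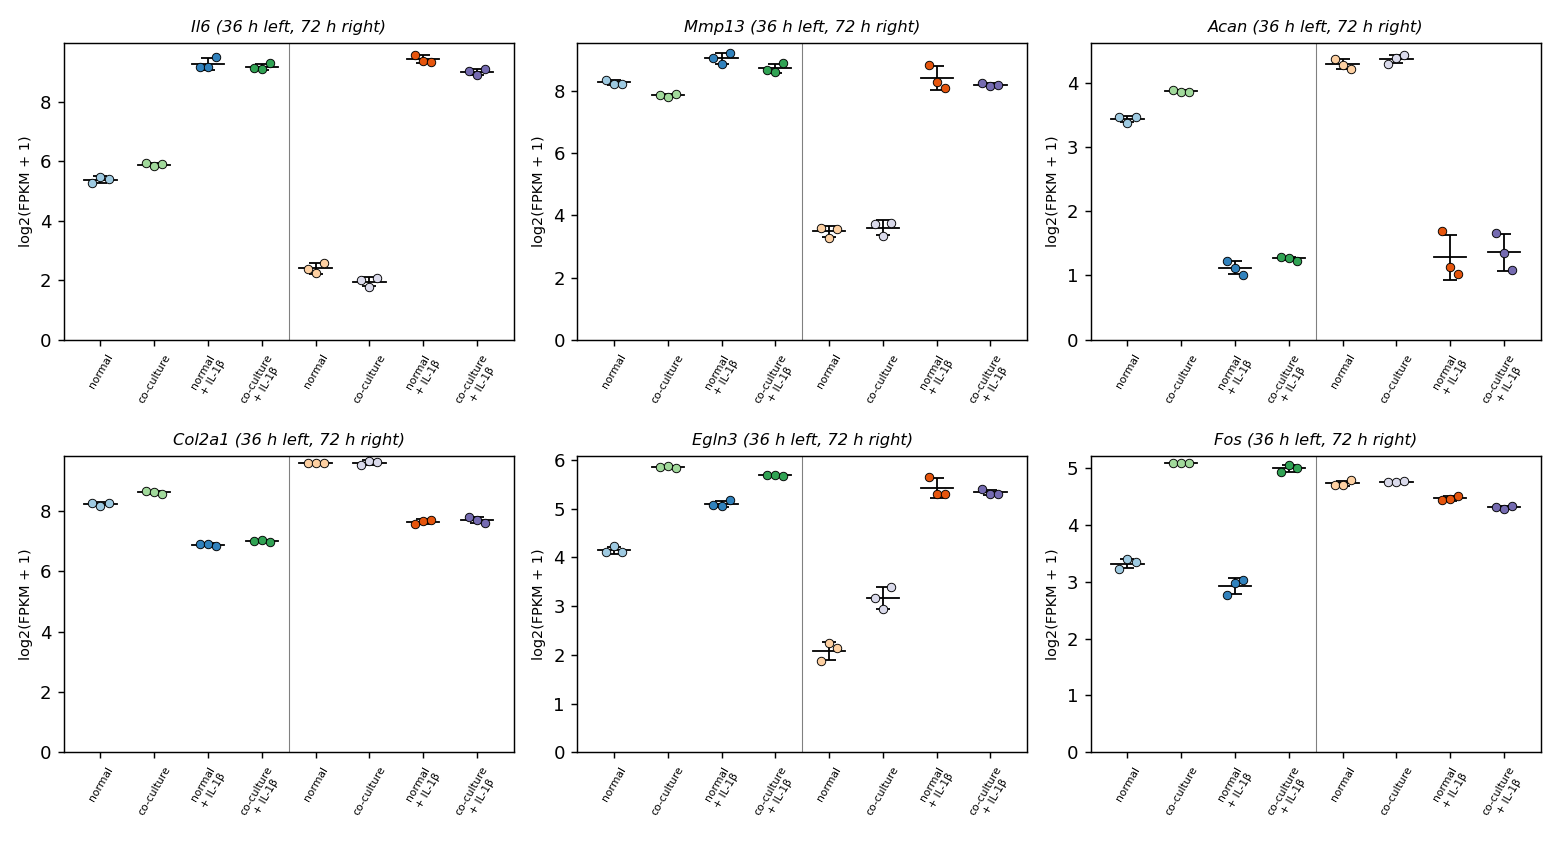
Values of log2(FPKM + 1) for Il6, Mmp13, Acan, Col2a1, Egln3 and Fos in each of the 24 libraries, by group, with 36 h left and 72 h right of the line in each panel; points are libraries, long bars the group means and whiskers the SD (n = 3). Untreated Mmp13 lies at 310.3 ± 16.2 FPKM at 36 h and 10.3 ± 1.34 at 72 h in normal culture, and Fos in co-culture without IL-1β at 33 ± 0.0529 against 8.98 ± 0.591 in normal culture at 36 h.

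Whether the IL-1β effect in normal culture differed between the times was tested directly. The rise was larger at 72 h for Lcn2 by 5.15 on the log2 scale, Mmp3 by 4.75, Mmp13 by 4.14, Saa3 by 4.11, the metalloreductase gene Steap4 by 3.73 and Il6 by 3.14. For Mmp3 the untreated level moved more than the treated one on the log2 scale: it was at 2803 ± 93.5 and 1440.4 ± 371 FPKM with IL-1β at 36 h and 72 h, and at 186 ± 24.8 and 2.55 ± 0.911 without. With IL-1β the levels of Lcn2, Mmp13, Saa3 and Steap4 were also lower at 72 h than at 36 h, and without it they fell further on that scale. The difference for Il6 likewise came mostly from a fall of the untreated level. In the other direction, the effect was lower at 72 h for Nqo1 by a difference of -2.16, Gsta4 -2.68, Klk10 -2.72, Perp -2.40, Ano3 -2.29 and Ltc4s -2.18. Ptgs2 differed by -1.10, Acan by -0.69 and Col2a1 by -0.56 (limma, adjusted p = 0.00309 or lower for these genes). By list, the difference was positive for 28 of 31 hypoxia and glycolysis genes (median 1.01, adjusted p = 1.21e-19, adjusted p = 0.0889 with an estimated correlation) and 27 of 34 cell cycle genes (median 0.77, adjusted p = 6.09e-10, adjusted p = 0.364 with an estimated correlation). The same held for 15 of 19 NF-kB genes (median 0.66, adjusted p = 5.50e-07, adjusted p = 0.00667 with an estimated correlation) and 9 of 12 skeletal muscle markers (median 0.70, adjusted p = 0.00183, adjusted p = 0.411 with an estimated correlation). It was negative for 15 of 21 TGF-beta and BMP response genes (median -0.56, adjusted p = 6.57e-07, adjusted p = 0.00667 with an estimated correlation) and 11 of 15 myofibroblast genes (median -0.58, adjusted p = 6.96e-07, adjusted p = 0.169 with an estimated correlation). These counts, adjusted over the list alone, were 29, 29, 15, 9, 15 and 13. The test passed for 5527 genes, 2891 with a more positive and 2636 with a more negative effect at 72 h.

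The untreated normal cultures themselves changed between 36 h and 72 h. Of the inflammatory genes 11 of 20 were lower at 72 h and 3 higher (median -0.77, camera adjusted p = 1.96e-05, adjusted p = 0.167 with an estimated correlation), and of the matrix-degrading enzymes 16 of 28 were lower and 4 higher (median -0.36, adjusted p = 1.96e-05, adjusted p = 0.00165 with an estimated correlation). Mmp3 fell by 5.74 on the log2 scale, Lcn2 by 5.63, Mmp13 by 4.79, Saa3 by 4.36, Steap4 by 4.53, Angptl4 by 4.12, Il6 by 2.99 and Nos2 by 1.09. Col2a1 rose from 302 ± 11.7 to 765 ± 3.38 FPKM, Acan from 9.85 ± 0.375 to 18.6 ± 1.03 and Col10a1 from 1.53 ± 0.207 to 7.52 ± 0.106, but the cartilage matrix list did not pass, with 5 of 21 genes higher and 10 lower (median -0.20, camera adjusted p = 0.0886, adjusted p = 0.544 with an estimated correlation). Ptgs2 and Prg4 rose by 1.24 and 0.72, and Col1a1 fell by 0.45. Among the largest rises were those of Klk10 (from 0.693 ± 0.127 to 11.2 ± 0.645 FPKM), Perp (from 0.48 ± 0.115 to 8.54 ± 0.263) and the gap junction gene Gjb2 (from 2.31 ± 0.204 to 19.5 ± 4.67). Fabp7 rose from 1.18 ± 0.276 to 10.8 ± 0.339, Tnfrsf11b, the decoy receptor osteoprotegerin, from 14.3 ± 0.762 to 73.9 ± 0.411 and Nqo1 from 16.1 ± 0.15 to 80.8 ± 4.11 (limma, adjusted p = 4.71e-06 or lower). All 34 cell cycle genes rose (median 1.01, camera adjusted p = 2.60e-14, adjusted p = 0.167 with an estimated correlation), with the ribonucleotide reductase subunit gene Rrm2 at 1.83. All 10 complement genes fell (median -2.35, camera adjusted p = 1.47e-11, adjusted p = 0.00165 with an estimated correlation), with C3 lower by 4.09. Of the NF-kB genes 16 of 19 fell (median -0.77, camera adjusted p = 1.67e-09, adjusted p = 0.00124 with an estimated correlation). Alongside, all 12 skeletal muscle markers fell (median -1.92, camera adjusted p = 8.89e-12, adjusted p = 0.0403 with an estimated correlation), Mylpf from 101 ± 5.57 to 14.7 ± 2.83 FPKM. Of the macrophage and leukocyte markers 14 of 17 rose (median 0.77, camera adjusted p = 2.61e-05, adjusted p = 0.0403 with an estimated correlation), with the macrophage receptor gene Csf1r from 0.893 ± 0.162 to 3.25 ± 0.305. Adjusted over the list alone, 12 inflammatory and 11 cartilage matrix genes were lower, and the other list counts were unchanged. In all, 7112 genes passed, 4027 higher and 3085 lower at 72 h.

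IL-1β was also compared with no IL-1β within co-culture. At 36 h Saa3 rose from 56.3 ± 6.7 to 7576 ± 45.1 FPKM, Il6 from 58.1 ± 1.87 to 576 ± 39.6, and Mmp3 from 108 ± 4.01 to 2493 ± 103. Nos2 rose from 3.35 ± 0.20 to 76.2 ± 1.46 and Ptgs2 from 95.7 ± 1.57 to 515 ± 19.7, and Ccl5 by 5.90 on the log2 scale. Col2a1 fell from 393 ± 11.9 to 128 ± 2.77 FPKM and Acan from 13.7 ± 0.193 to 1.4 ± 0.0473, and Msmp, Mest and the proenkephalin gene Penk had log2 changes of -4.10, -4.08 and -3.06. At 72 h Saa3 rose by 11.79, Lcn2 by 9.65, Mmp3 by 9.10, Il6 by 7.05, Nos2 by 6.78, the haptoglobin gene Hp by 5.65 and Mmp13 by 4.60. Mest, Eln, Ccn3, Acan and Col2a1 fell by 3.43, 3.43, 3.06, 3.01 and 1.91 (limma, adjusted p = 2.10e-11 or lower for the named genes at 36 h and 4.75e-15 or lower at 72 h). Inflammatory genes rose in 18 of 20 cases at 36 h (median 2.46, camera adjusted p = 1.21e-14, adjusted p = 0.0273 with an estimated correlation) and in 19 at 72 h (median 3.5, adjusted p = 2.08e-20, adjusted p = 0.00797 with an estimated correlation). NF-kB genes rose in 14 of 19 (median 0.66, adjusted p = 8.56e-10, adjusted p = 0.000965 with an estimated correlation) and 17 (median 0.97, adjusted p = 1.55e-17, adjusted p = 2.56e-05 with an estimated correlation). Cartilage matrix genes fell in 17 of 21 cases at 36 h (median -1.06, adjusted p = 1.11e-05, adjusted p = 0.269 with an estimated correlation) and 18 at 72 h (median -1.04, adjusted p = 2.12e-07, adjusted p = 0.118 with an estimated correlation). Cell cycle genes fell in 30 of 34 (median -0.74, adjusted p = 8.97e-09, adjusted p = 0.394 with an estimated correlation) and 29 (median -0.42, adjusted p = 2.88e-05, adjusted p = 0.453 with an estimated correlation). With adjustment over the list alone, 31 and 30 cell cycle genes were lower, and the other counts were as given. At 36 h 7145 genes passed (2847 higher, 4298 lower) and at 72 h 5978 (2249 higher, 3729 lower). The splits were 2254 to 5299 and 1719 to 5460 after TPM rescaling, and 3293 to 3573 and 2571 to 3032 after median-of-ratios scaling.

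The next comparison asked what the fibroblasts did to untreated chondrocytes at 36 h. Genes of the hypoxia and glycolysis list rose in co-culture: Egln3 rose from 16.7 ± 0.907 to 56.9 ± 0.946 FPKM and Car9, a carbonic anhydrase that hypoxia induces, from 95.4 ± 4.44 to 203 ± 0.298. Ndrg1 rose from 42.6 ± 2.26 to 87.2 ± 4.43, Ankrd37 from 3.37 ± 0.393 to 8.73 ± 0.51 and Vegfa, the vascular endothelial growth factor, from 77.3 ± 4.6 to 126 ± 1.52. In all, 28 of 31 genes of this list rose and none fell (median 0.46, camera adjusted p = 2.82e-39, adjusted p = 0.0385 with an estimated correlation), and 30 rose when adjusted over the list alone. Some transcription factor genes that cells switch on within minutes of a stimulus were also higher: Fos rose from 8.98 ± 0.591 to 33 ± 0.0529 FPKM, Egr1 from 62.7 ± 3.09 to 202 ± 7.46 and Nr4a1 from 21.5 ± 1.69 to 72.3 ± 2.09. Ptgs2 rose from 20.5 ± 1.31 to 95.7 ± 1.57 FPKM and Lif from 2.82 ± 0.257 to 11.1 ± 0.529. Il6 rose by 0.50 on the log2 scale and Nos2 by 0.89, while Mmp3, Mmp13 and Saa3 fell by 0.77, 0.41 and 0.93. Col2a1 rose from 302 ± 11.7 to 393 ± 11.9 FPKM and Acan from 9.85 ± 0.375 to 13.7 ± 0.193 (limma, adjusted p = 0.0495 or lower, the highest for Mmp13).

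Complement genes fell in 7 of 10 cases at 36 h (median -0.35, camera adjusted p = 3.88e-05, adjusted p = 0.0716 with an estimated correlation), among them C3 by 0.53 and C4b by 0.56. WNT pathway genes fell in 9 of 19 with 1 higher (median -0.24, camera adjusted p = 0.000216, adjusted p = 0.0786 with an estimated correlation), among them Sfrp2 by 1.33 and Sfrp1 by 0.67. Myofibroblast and actin cytoskeleton genes rose in 5 of 15 cases (median 0.15, camera adjusted p = 6.41e-06, adjusted p = 0.321 with an estimated correlation). TGF-beta and BMP response genes rose in 6 of 21 cases and fell in 3 (median 0.06, camera adjusted p = 0.0496, adjusted p = 0.321 with an estimated correlation). Of all lists 7 passed with camera in this comparison, 4 higher and 3 lower. With the replicate block 5 passed, 2 higher and 3 lower, so not every higher list given here held. Ccn2 rose from 139 ± 2.15 to 257 ± 2.58 FPKM. Of the dermal fibroblast markers, 8 of 23 fell and 3 rose (median -0.15, camera adjusted p = 0.0372, adjusted p = 0.404 with an estimated correlation). Dpt of this list fell by 0.99 and the chemokine gene Cxcl12, a member of the inflammatory list, by 0.77. Adjusted over the list alone, 8 complement genes, 11 WNT genes and 9 dermal fibroblast markers fell, and 6 myofibroblast and 7 TGF-beta genes rose. Among the largest falls of single genes were those of the angiotensin receptor gene Agtr2 (by 1.53), Egfl6 (1.23), Sned1 (1.20), Msmp (1.20) and Igfbp3 (1.17). Adamts5 rose by 0.21. Sox9 (26.1 ± 0.464 against 30.3 ± 0.896 FPKM), Adamts4 (8.26 ± 0.284 against 9.21 ± 0.403), Prg4 (32.1 ± 1.05 against 30.4 ± 2.37), Col1a1 (2390.2 ± 10.1 against 2489 ± 41.8) and Col10a1 (1.19 ± 0.138 against 1.53 ± 0.207) did not pass (adjusted p between 0.0817 and 0.535). The threshold was passed by 1885 genes, 765 higher and 1120 lower, of which 26 and 8 changed at least 2-fold. After median-of-ratios scaling 889 rose and 786 fell, and without replicate 1 of the untreated normal cultures 1255 genes passed. The calls of Mmp13 and Adamts5 ended without any 1 of the 6 libraries, and that of Acan without any 1 of 5.

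At 72 h fewer genes differed between untreated co-culture and normal culture than at 36 h. The hypoxia and glycolysis genes were again higher, in 21 of 31 cases (median 0.36, camera adjusted p = 2.35e-31, adjusted p = 0.0941 with an estimated correlation) and 27 when adjusted over the list alone. Egln3 rose from 3.27 ± 0.528 to 8.09 ± 1.41 FPKM and Car9 from 8.56 ± 0.257 to 18.6 ± 4.57. Further rises were those of Ndufa4l2 (from 42.2 ± 1.91 to 76 ± 7.17), Ankrd37 (from 2.03 ± 0.423 to 4.31 ± 1.03) and the mitophagy gene Bnip3 (from 119 ± 2.3 to 173 ± 17.1). The stress-response genes Stc2, Adm2, Trib3 and Shmt2 rose by 0.81, 0.64, 0.49 and 0.44. Prg4 fell from 50.5 ± 1.02 to 32.4 ± 0.991 FPKM, Saa3 from 4.62 ± 2.35 to 0.883 ± 0.137, Mmp3 from 2.55 ± 0.911 to 1.28 ± 0.254 and Il6 from 4.29 ± 0.652 to 2.87 ± 0.416 (limma, adjusted p = 0.0376 or lower).

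Of the p53 target and senescence genes 5 of 19 fell (median -0.12, camera adjusted p = 9.15e-05, adjusted p = 0.332 with an estimated correlation), and 9 when adjusted over the list alone, among them Ccng1 by 0.40 and Trp53inp1 by 0.52. The synovial lining markers fell in 2 of 8 cases (median -0.18, camera adjusted p = 0.00816, adjusted p = 0.332 with an estimated correlation), with Cd55 lower by 0.53. The dermal fibroblast markers fell in 3 of 23 (median -0.05, camera adjusted p = 0.0113, adjusted p = 0.332 with an estimated correlation). Skeletal muscle markers were higher in 3 of 12 cases (median 0.28, camera adjusted p = 5.97e-06, adjusted p = 0.332 with an estimated correlation). Of these Mylpf rose from 14.7 ± 2.83 to 20.8 ± 0.698 FPKM, and the myoglobin gene Mb, which is on none of the lists, from 3.49 ± 0.349 to 5.98 ± 1.2. The last counts, adjusted over the list alone, were 2, 6 and 7. Angptl7, Sncg, Slurp1, Ndnf and Cxcl5 fell by 0.68, 0.67, 0.67, 0.56 and 0.54. The other core genes did not pass: Col2a1 stood at 777 ± 38.5 against 765 ± 3.38 FPKM, Acan at 19.8 ± 0.946 against 18.6 ± 1.03, and Sox9 at 23.5 ± 0.692 against 26.4 ± 1.91. Mmp13 stood at 11.2 ± 1.95 against 10.3 ± 1.34, Adamts4 at 4.16 ± 0.20 against 4.42 ± 0.18, and Adamts5 at 23.2 ± 0.358 against 25 ± 0.945. Ptgs2 stood at 49.99 ± 3.46 against 50.03 ± 5.69, Nos2 at 0.010 ± 0 against 0.10 ± 0.0557, Col1a1 at 2003 ± 50.1 against 1820.5 ± 38.3 and Col10a1 at 5.37 ± 0.291 against 7.52 ± 0.106. In all 414 genes passed, 210 higher and 204 lower, 159 and 270 after TPM rescaling and 252 and 160 after median-of-ratios scaling. Of the genes called at 36 h, 105 were higher at both times (13.2 for independent lists) and 82 lower at both (18.8), while 18 passed in opposite directions. Leaving out any 1 of the 6 libraries reduced the count at 72 h to between 153 and 221 genes, while the spread of the 6 compared libraries gave 1330, against 3095 at 36 h. Leaving out any 1 of them ended the calls of Ankrd37 and Trp53inp1, and leaving out some of them those of Il6, Mmp3 and Mylpf.

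**Figure D3:**
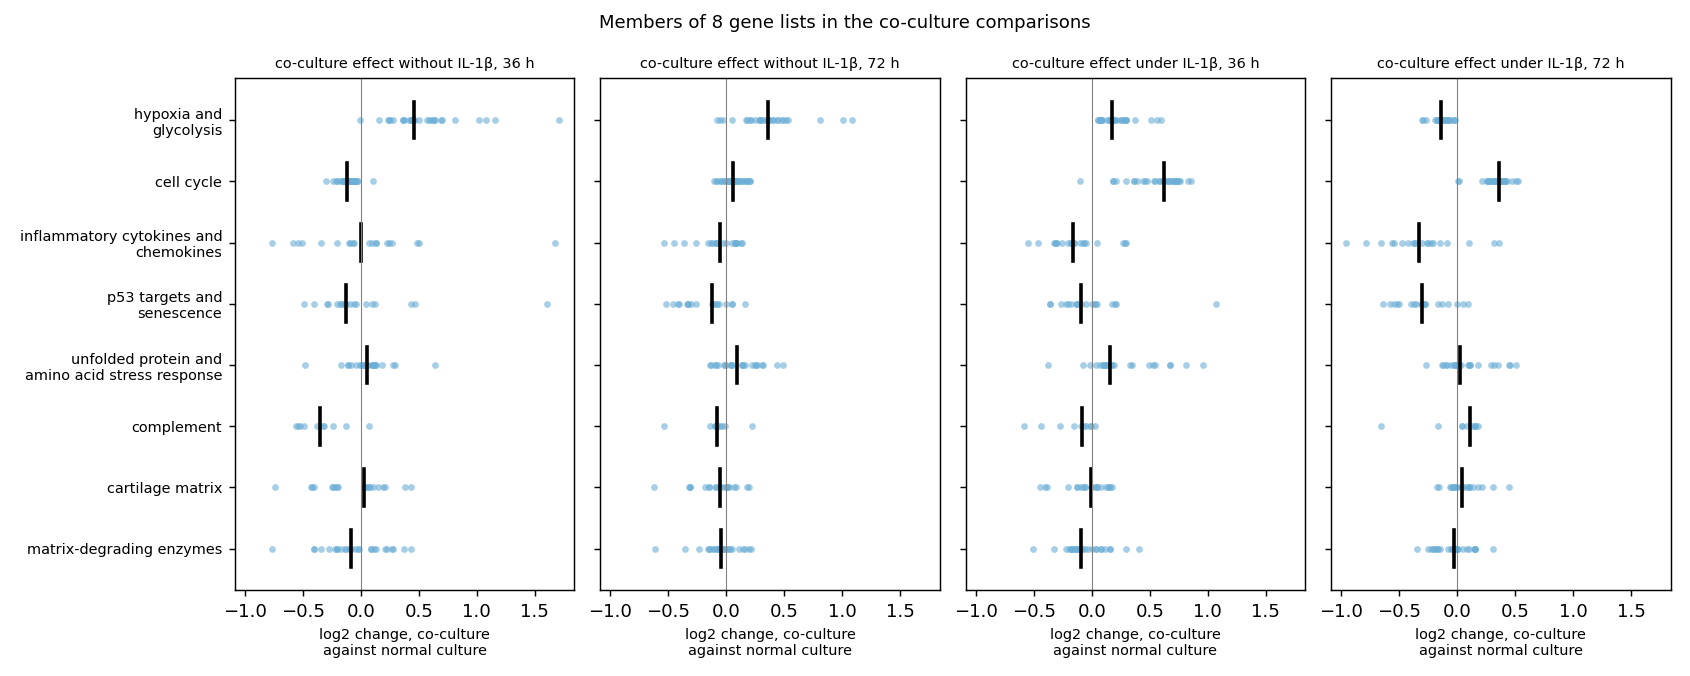
Log2 changes in co-culture against normal culture for the tested members of 8 gene lists in the 4 co-culture comparisons; each point is a gene and each bar the median of its list. The hypoxia and glycolysis medians are 0.46, 0.36, 0.18 and -0.14 from left to right, and the cell cycle medians -0.12, 0.06, 0.63 and 0.36.

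The main question of the design was what fibroblast co-culture does to chondrocytes under IL-1β. At 36 h cell cycle genes were higher in co-culture in 29 of 34 cases and lower in none (median 0.63, camera adjusted p = 5.59e-31, adjusted p = 0.171 with an estimated correlation), and in 32 when adjusted over the list alone. Birc5, which encodes survivin, rose from 7.78 ± 1.75 to 14.7 ± 1.29 FPKM and the cyclin gene Ccna2 from 6.38 ± 0.435 to 12.1 ± 0.14. The mitotic kinase gene Plk1 rose from 5.11 ± 0.587 to 9.36 ± 0.488 and Cdc20 from 8.48 ± 0.627 to 15 ± 0.806. The transcription factor genes Fos (from 6.61 ± 0.715 to 30.8 ± 1.49 FPKM), Egr1 (from 55 ± 4.48 to 217 ± 5.55) and Egr2 (from 1.88 ± 0.402 to 8.28 ± 0.171) were among the genes with the largest rises. So were Ier2 (from 29.8 ± 1.74 to 98.1 ± 5.3), Nr4a1 (from 38.9 ± 0.808 to 114 ± 2.3) and Zfp36, which promotes decay of cytokine transcripts (from 27.7 ± 1.74 to 66.7 ± 3.58). Of the main IL-1β-responsive genes several did not pass: Il6 stood at 576 ± 39.6 against 621 ± 87.4 FPKM, Mmp3 at 2493 ± 103 against 2803 ± 93.5, and Mmp13 at 428 ± 43.9 against 536 ± 66.6. Ptgs2 stood at 515 ± 19.7 against 554 ± 53.1, Nos2 at 76.2 ± 1.46 against 95.3 ± 6.61, Col2a1 at 128 ± 2.77 against 117 ± 3.83 and Acan at 1.4 ± 0.0473 against 1.18 ± 0.155 (limma, adjusted p from 0.0835 for Nos2 to 0.761 for Ptgs2).

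Unfolded protein and amino acid stress genes rose in 13 of 24 cases at 36 h and fell in 1 (median 0.16, camera adjusted p = 1.13e-09, adjusted p = 0.128 with an estimated correlation). Trib3 rose by 0.96, the serine synthesis genes Psat1 and Phgdh by 0.81 and 0.67, and Shmt2 by 0.68. Hypoxia and glycolysis genes rose in 14 of 31 cases (median 0.18, camera adjusted p = 3.70e-10, adjusted p = 0.242 with an estimated correlation), and 19 when adjusted over the list alone. Egln3 rose from 33.2 ± 1.52 to 50.7 ± 0.334 FPKM and the kinase gene Pdk1 from 30.7 ± 3.04 to 39.95 ± 0.546. Inflammatory genes fell in 6 of 20 cases and rose in 1 (median -0.16, camera adjusted p = 0.0025, adjusted p = 0.309 with an estimated correlation), and 7 and 2 when adjusted over the list alone. Cx3cl1 fell by 0.55 and Cxcl1 from 1512 ± 34.2 to 1212 ± 24.1 FPKM. Hypertrophy and mineralization genes fell in 6 of 18 cases (median -0.10, camera adjusted p = 0.00175, adjusted p = 0.242 with an estimated correlation). Spp1, which encodes osteopontin, fell from 1954 ± 141 to 1415 ± 84.1 FPKM and Col10a1 from 2.26 ± 0.248 to 1.24 ± 0.214 (adjusted p = 0.0136 or lower), the latter a call that ended without any 1 of 3 libraries. Skeletal muscle markers were lower in 2 of 12 cases (median -0.26, camera adjusted p = 0.000224, adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 7 hypertrophy and 7 muscle genes fell and 13 unfolded protein and amino acid stress genes rose. Prg4 fell by 0.40 and Igfbp5 by 0.64, and among the largest falls were those of Penk (0.95), the mast cell protease gene Mcpt8 (0.91), the splicing kinase gene Clk1 (0.82), the granzyme gene Gzme (0.72), Agtr2 (0.65) and Icosl (0.65). Sox9 (5.23 ± 0.27 against 6.4 ± 0.271 FPKM), Adamts4 (11.5 ± 0.587 against 12.9 ± 0.206), Adamts5 (49.6 ± 0.724 against 52.8 ± 3.27) and Col1a1 (1753 ± 50.3 against 1623 ± 82.1) did not pass. In all 1285 genes passed, 777 higher and 508 lower, 12 of the higher and 0 of the lower at least 2-fold. Leaving out replicate 1 of the IL-1β-treated normal cultures gave 738, the lowest count, and replicates 1, 2 and 3 of the co-cultures 831, 835 and 771.

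At 72 h under IL-1β, inflammatory genes stood lower in co-culture, but the calls rest on the spread of all 24 libraries, without pairing by replicate number. Il6 was at 512 ± 37.9 against 687 ± 61.3 FPKM in co-culture and normal culture (log2 difference -0.42, SE 0.10, limma adjusted p = 0.00817). Nos2 was at 109.9 ± 3.69 against 178 ± 55.2 (adjusted p = 0.00158) and Prg4 at 90.7 ± 4.88 against 103 ± 1.21 (adjusted p = 0.0223). Without replicate 1 of the IL-1β-treated normal cultures, or replicate 2 of the co-cultures, the calls of Il6 and Prg4 ended. Without the former the log2 difference of Nos2 went from -0.65 to -0.41. With that spread 12 of 20 inflammatory genes fell and 1 rose (median -0.33, camera adjusted p = 1.29e-08, adjusted p = 0.128 with an estimated correlation). Of the p53 target and senescence genes 12 of 19 fell (median -0.31, camera adjusted p = 2.64e-11, adjusted p = 0.044 with an estimated correlation). Cell cycle genes rose in 24 of 34 cases (median 0.36, camera adjusted p = 9.40e-14, adjusted p = 0.264 with an estimated correlation). In all 1520 genes passed, 879 higher and 641 lower (642 and 876 after median-of-ratios scaling), of which 1 changed at least 2-fold. With the spread of the 6 compared libraries alone, limma called 0 genes (1418 genes, 11.6%, at an unadjusted p under 0.05, smallest adjusted p 0.163). With the replicate number as a block, tried because same-numbered libraries of these groups deviated together, it also called 0 (2752 genes, 22.6%, smallest adjusted p 0.05003). With the spread of all 24 libraries the count was 613 without replicate 1 and 2461 without replicate 3 of the IL-1β-treated normal cultures, and 889 and 593 without replicates 1 and 2 of the co-cultures.

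Genes called with the 24 libraries at 72 h under IL-1β included, among inflammatory genes, Csf3 (lower by 0.65), Il1a (0.56) and Cxcl3 (0.79), and, among p53 targets, Gdf15 (0.58), Mdm2 (0.52) and Perp (0.64). NF-kB genes fell in 4 of 19 cases (median -0.11, camera adjusted p = 0.000251, adjusted p = 0.044 with an estimated correlation), with the adhesion gene Icam1 lower by 0.50. Synovial lining markers fell in 5 of 8 (median -0.23, camera adjusted p = 4.48e-05, adjusted p = 0.0483 with an estimated correlation), with Cd55 and Pdpn lower by 0.66 and 0.36. NRF2 and antioxidant genes fell in 5 of 20 (median -0.21, camera adjusted p = 6.24e-07, adjusted p = 0.104 with an estimated correlation), with Hmox1 lower by 0.49. Il11, the hyaluronan synthase gene Has1, Procr, Penk and Cd80 were lower by 0.96, 0.82, 0.80, 0.77 and 0.72. Cth, Car6, Mest and the amino acid transporter gene Slc7a5 were higher by 0.85, 0.71, 0.71 and 0.65, and Ccna2 and Kif11 by 0.51 and 0.48. Skeletal muscle markers were higher in 4 of 12 cases (median 0.26, camera adjusted p = 0.00232, adjusted p = 0.35 with an estimated correlation), and Mb and Myl1, on none of the lists, by 0.75 and 0.54. Hypoxia and glycolysis genes were lower in 6 of 31 cases (median -0.14, camera adjusted p = 1.62e-07, adjusted p = 0.295 with an estimated correlation). Adjusted over the list alone, 15 inflammatory, 15 p53, 6 NF-kB, 5 synovial, 11 NRF2 and 7 hypoxia genes were lower and 32 cell cycle and 5 muscle genes higher. The hypertrophy and mineralization list, with 4 of 18 genes lower, passed with the block only (adjusted p = 0.0544 without and adjusted p = 0.0396 with it), and not with an estimated correlation (adjusted p = 0.386). Replicates 1 and 3 of the IL-1β-treated normal cultures deviated most from their group, with a residual SD of 0.159 and 0.142 on the log2 scale. Replicate 3 of the IL-1β-treated normal and co-cultures had the highest FPKM sums (506621 and 504696). Without replicate 1 of the IL-1β-treated normal cultures 7 cell cycle genes were higher and 7 inflammatory, 9 p53 and 1 hypoxia genes lower. The calls of Csf3, Sox9 and Col10a1 then ended (log2 differences of -0.29, -0.11 and -0.15). Those of Il11, Cxcl3, Mdm2, Icam1, Slc7a5 and Ccna2 held at -0.60, -0.47, -0.32, -0.23, 0.38 and 0.27. None of the list members passed with the 6 libraries alone. Sox9 (6.31 ± 0.315 against 7.98 ± 1.91 FPKM, adjusted p = 0.0433) and Col10a1 (2.27 ± 0.108 against 3.54 ± 1.6, adjusted p = 0.0498) passed narrowly. Those that did not pass were Col2a1 (207 ± 14 against 200.01 ± 10.9), Acan (1.61 ± 0.517 against 1.48 ± 0.642), Mmp3 (1249 ± 97.5 against 1440.4 ± 371), and Mmp13 (293 ± 10.2 against 348 ± 96.7). Nor did Adamts4 (7.38 ± 0.584 against 7.53 ± 0.238), Adamts5 (19.5 ± 1.76 against 17.4 ± 2.38), Ptgs2 (439 ± 55.1 against 643 ± 260.3, adjusted p = 0.0547) and Col1a1 (1630.3 ± 19.9 against 1513 ± 123).

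The IL-1β-responsive genes were also tested as 2 sets chosen in other libraries, the 461 genes raised and the 478 lowered at least 2-fold by IL-1β at 36 h in normal culture. At 72 h under IL-1β, 392 of the 461 raised genes were lower in co-culture (median fell by 0.20 on the log2 scale, fry adjusted p = 1.75e-05 over 8 such tests, unadjusted 3.19e-06). Of the 478 lowered genes 404 were higher (median 0.22, adjusted p = 1.75e-05, unadjusted 4.37e-06). With the 6 libraries alone the fry adjusted p was 0.0385 for both sets (unadjusted 0.0192 and 0.0131), and with the replicate block 0.0689 for both (unadjusted 0.0556 and 0.0689), which did not pass the threshold. These p-values were adjusted together, over both sets with and without the block, and not over the 8 tests. The interaction of co-culture and IL-1β at 72 h had medians of -0.14 (adjusted p = 0.00601) and 0.21 (adjusted p = 0.000993). These became -0.0866 and 0.136 without replicate 1 of the IL-1β-treated normal cultures at 72 h, and after TPM rescaling the raised set no longer passed (median -0.113, unadjusted p = 0.0834). The corresponding sets from 72 h, tested under IL-1β at 36 h, had medians of -0.04 (adjusted p = 0.702) and -0.04 (adjusted p = 0.953), and of -0.12 (adjusted p = 0.0190) and 0.13 (adjusted p = 0.00969) in the interaction at 36 h. With an estimated correlation the last 2 had camera adjusted p = 0.0546 and adjusted p = 0.259. The mean of the raised set at 72 h was 4.34, 4.14 and 4.15 in the 3 IL-1β-treated normal cultures and 4.01, 3.99 and 4.02 in the co-cultures, a separation for which an exact permutation test of 3 against 3 cannot give less than 0.1.

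**Figure D4:**
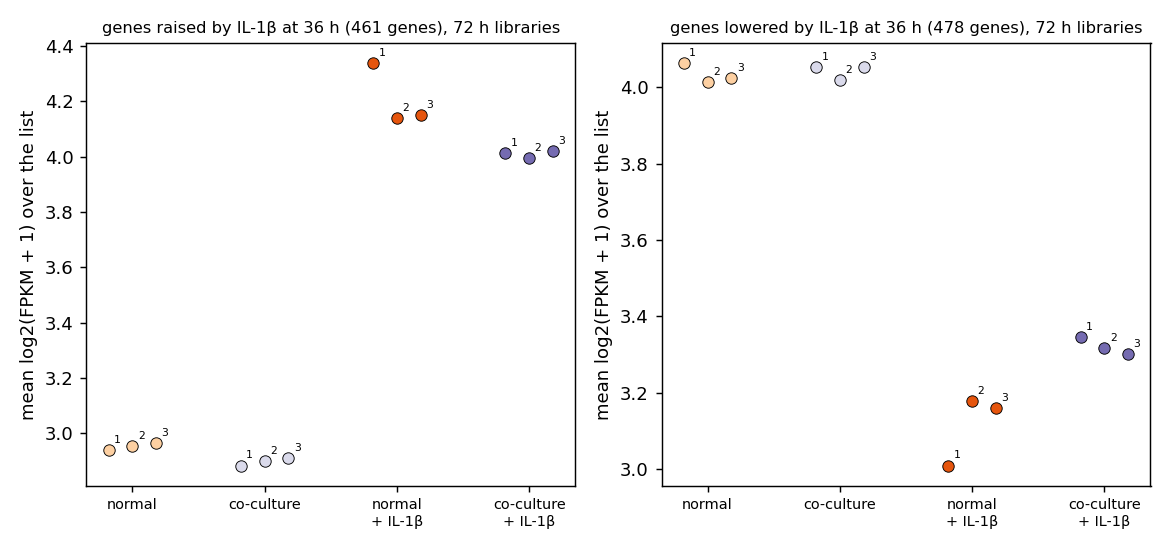
Mean log2(FPKM + 1) over the 461 genes raised (left) and the 478 genes lowered (right) by IL-1β at 36 h, in each of the 12 libraries collected at 72 h; each point is 1 library with its replicate number, and the vertical axes do not start at 0. In the left panel the IL-1β-treated co-cultures lie at 3.99 to 4.02 and the IL-1β-treated normal cultures at 4.14 to 4.34, with untreated libraries between 2.88 and 2.96.

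Between 36 h and 72 h the co-culture effect under IL-1β itself was compared. Fos, Egr1, Egr2, Nr4a1 and Ier2, raised in co-culture at 36 h, had differences of -2.22, -2.10, -2.10, -2.03 and -1.67, and Otor, Mb and Myl1 of 1.05, 1.01 and 0.87 (limma, adjusted p = 0.000924 or lower). Both cultures moved: with IL-1β Fos went from 6.61 ± 0.715 FPKM at 36 h to 21.04 ± 0.624 at 72 h in normal culture and from 30.8 ± 1.49 to 18.8 ± 0.378 in co-culture, and Egr1 from 55 ± 4.48 to 157 ± 3.32 and from 217 ± 5.55 to 143 ± 3.99. Hypoxia and glycolysis genes had a negative difference in 12 of 31 cases (median -0.32, camera adjusted p = 5.19e-23, adjusted p = 0.148 with an estimated correlation). Skeletal muscle markers had a positive one in 3 of 12 (median 0.50, adjusted p = 4.35e-09, adjusted p = 0.152 with an estimated correlation). The counts were 25 and 11 when adjusted over the list alone. The test passed for 317 genes, 132 with a more positive and 185 with a more negative effect at 72 h, and after median-of-ratios scaling 104 and 222. With the spread of the 12 compared libraries limma called 83, and without 1 library the count ran from 167 to 571. Among genes called at 36 h and 72 h under IL-1β, 307 were higher in co-culture at both times (56.1 for independent lists) and 108 lower at both (26.7), while 46 passed in opposite directions. The 72 h calls in this overlap rest on the spread of all 24 libraries, since the 6 compared libraries gave 0 (1418 at an unadjusted p under 0.05).

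Whether the co-culture effect differed with and without IL-1β was tested as an interaction. At 36 h the interaction was positive for 28 of 34 cell cycle genes (median 0.73, camera adjusted p = 1.56e-27, adjusted p = 0.175 with an estimated correlation). It was negative for 13 of 31 hypoxia and glycolysis genes (median -0.35, adjusted p = 7.72e-19, adjusted p = 0.175 with an estimated correlation) and 6 of 21 TGF-beta and BMP response genes (median -0.16, adjusted p = 3.16e-06, adjusted p = 0.0206 with an estimated correlation). At 72 h it was negative for 22 of 31 hypoxia and glycolysis genes (median -0.48, adjusted p = 3.88e-35, adjusted p = 0.0303 with an estimated correlation) and 1 of 19 NF-kB genes (median -0.20, adjusted p = 5.10e-06, adjusted p = 0.0143 with an estimated correlation). Among single genes Ptgs2 (-2.27), Lif (-1.38), Nos2 (-1.21), Egln3 (-1.11) and Il6 (-0.60) had negative and Sfrp2 (1.22) and Igfbp3 (1.14) positive interactions at 36 h. At 72 h Car9 (-1.18) and Egln3 (-1.17) had negative and Saa3 (1.34) and Prg4 (0.45) positive ones (limma, adjusted p = 0.00935 or lower at 36 h and 0.00894 or lower at 72 h). Without IL-1β at 36 h, Ptgs2, Lif, Nos2, Egln3 and Il6 were higher and Sfrp2 and Igfbp3 lower in co-culture. Under IL-1β at 36 h Ptgs2, Nos2 and Il6 did not pass between the cultures, and Egln3 was higher in co-culture. Without IL-1β at 72 h, Car9 and Egln3 were higher and Saa3 and Prg4 lower in co-culture, with Saa3 near 0 (0.883 ± 0.137 against 4.62 ± 2.35 FPKM). Adjusted over the list alone the list counts were 32, 20 and 7 at 36 h and 28 and 5 at 72 h. At 36 h 847 genes passed (576 positive, 271 negative, and 1793 with the spread of the 12 compared libraries) and at 72 h 379 (205 positive, 174 negative, or 185 and 97 after TPM rescaling and 111 and 265 after median-of-ratios scaling). At 72 h limma called 12 genes with the spread of the 12 compared libraries, and counts without 1 library ran from 107 (without replicate 1 of the IL-1β-treated co-cultures at 72 h) to 1167 (without replicate 2 of the IL-1β-treated normal cultures at 72 h).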

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

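The tests of dermal fibroblast RNA, of the spread at 72 h, of the omission of single libraries and of other splits of the libraries were chosen after the results were seen, as was the list of immediate early genes, while the tests of scaling and of brief disturbance were written before their values were seen. The interactions and differences between times in this part were picked out because an effect differed between 2 groups by a test of the difference itself. The immediate early genes, the hypoxia and glycolysis genes without IL-1β, the co-culture effect under IL-1β at 72 h and the other splits were taken up outside that rule.

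At 36 h the co-culture effect differed with and without IL-1β for 847 genes. Among the named genes the interaction was positive for Sfrp2 (1.22), Gins1 (1.16), Igfbp3 (1.14), Msmp (1.08), Birc5 (1.01), Sned1 (1.00) and Mcm5 (0.94), and negative for Ptgs2 (-2.27), Lif (-1.38), Tnfrsf9 (-1.33), Nos2 (-1.21), Egln3 (-1.11), Cck (-1.04), Il6 (-0.60) and Prg4 (-0.48). Without IL-1β, Sfrp2, Igfbp3, Msmp and Sned1 were lower and Ptgs2, Lif, Nos2, Egln3 and Il6 higher in co-culture. Under IL-1β, Ptgs2, Nos2 and Il6 did not pass between the cultures, and Egln3 was higher in co-culture. With the spread of the 12 compared libraries limma called 1793, and the call of Msmp ended without either of 2 libraries. The median of the cell cycle list was 0.73 and that of the hypoxia and glycolysis list -0.35, and neither list passed with an estimated correlation (camera adjusted p = 0.175 and adjusted p = 0.175). At 72 h the effect differed for 379 genes with the spread of all 24 libraries but for 12 with that of the 12 compared ones, and for 107 to 1167 without 1 library. It was positive for Saa3 (1.34), Mest (0.85), Mme (0.75), Slc1a3 (0.58), Itih5 (0.58), Atad2 (0.57) and Prg4 (0.45), and negative for Car9 (-1.18), Egln3 (-1.17), Ndufa4l2 (-0.93), Mgarp (-0.82), Gpr35 (-0.76), Upp1 (-0.73), Slc16a3 (-0.69) and Bnip3 (-0.67). Without IL-1β at 72 h, Saa3 and Prg4 were lower in co-culture (log2 changes of -1.49 and -0.62), and Car9, Egln3, Ndufa4l2 and Bnip3 higher. Saa3 was near 0 there, at 0.883 ± 0.137 against 4.62 ± 2.35 FPKM. The calls of Mest, Atad2 and Mgarp ended without some single libraries. The list medians were 0.29 and -0.48 (adjusted p = 0.633 and adjusted p = 0.0303 with an estimated correlation).

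The IL-1β effect in normal culture differed between 72 h and 36 h for 5527 genes, with Lcn2 (5.15), Mmp3 (4.75), Mmp13 (4.14), Saa3 (4.11), Steap4 (3.73) and Il6 (3.14) more positive at 72 h and Klk10 (-2.72), Gsta4 (-2.68), Perp (-2.40), Ano3 (-2.29), Ltc4s (-2.18), Nqo1 (-2.16), Ptgs2 (-1.10), Acan (-0.69) and Col2a1 (-0.56) more negative. For Lcn2, Mmp3, Mmp13, Saa3 and Steap4 the IL-1β-treated level was lower at 72 h, and the untreated level fell further on the log2 scale. The co-culture effect under IL-1β differed between the times for 317 genes (83 with the spread of the 12 compared libraries, 167 to 571 without 1 library), with Fos (-2.22), Egr1 (-2.10), Egr2 (-2.10), Nr4a1 (-2.03), Ier2 (-1.67) and Dusp5 (-1.57) more negative at 72 h and Otor (1.05), Mb (1.01), Myl1 (0.87), Clk1 (0.82), Mylpf (0.78) and Mest (0.76) more positive. The call of Mest ended without any 1 of 8 libraries.

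Many immediate early genes, switched on within minutes of many stimuli, had higher values in co-culture at 36 h: of a list of 20 fixed after its members' values had been seen, 18 rose without IL-1β (median 0.87) and 16 rose and 3 fell under IL-1β (median 0.86). Over all 27 tested candidate genes 23 rose without IL-1β (median 0.70), and 19 rose and 3 fell under it (median 0.44). Both lists were prompted by genes that stood out in these comparisons, so the counts describe and no list p-value is given. The tables argue against the authors' scaling, since the smallest median over 2 other scalings and both comparisons was 0.844. Brief disturbance of the cultures at collection cannot be told apart from a lasting signal of the fibroblasts: later targets of the ERK pathway had medians of 0.16 without IL-1β (fry adjusted p = 0.00176, over the 13 comparisons of this list) and 0.0456 under it (adjusted p = 0.169). The second lay below the bound of 0.1 set for a disturbance, which had to hold in both, and the first between that bound and the 0.2 set against it. At 72 h 2 of the 20 genes were higher and 2 lower without IL-1β (median 0.0142), and in untreated normal culture 13 were higher and 2 lower at 72 h than at 36 h (median 0.24). Under IL-1β at 72 h 13 were lower and 0 higher (median -0.27), with the spread of all 24 libraries, in a comparison where limma called 0 genes with the 6 compared libraries (1418 at an unadjusted p under 0.05). The order of collection and the co-culture medium were not given in the sources used here and remain open.

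Hypoxia and glycolysis genes were higher in co-culture without IL-1β at both times, with medians of 0.46 and 0.36, though with an estimated correlation the list passed at 36 h only (camera adjusted p = 0.0385 and adjusted p = 0.0941). Against the authors' scaling, the smallest median over 2 other scalings and both times was 0.321. RNA from dermal fibroblasts in the chondrocyte samples cannot be told apart by these data, since all 23 markers of the list passed the expression filter in these cultures (4 are also on another list) and the profile of these fibroblasts was not measured, although the larger median of the markers was -0.0545. An effect of the fibroblasts stays open, untested. The interaction of this list with IL-1β at 72 h passed with the spread of all 24 libraries (camera adjusted p = 3.88e-35, adjusted p = 0.0303 with an estimated correlation). With that of the 12 compared libraries limma called 12 genes in all. List means at 72 h overlapped under IL-1β (normal culture 7.165, 6.829 and 6.932, co-culture 6.828, 6.813 and 6.878). Without IL-1β they did not (normal culture 5.82, 5.82 and 5.85, co-culture 6.18, 6.12 and 6.27).

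The co-culture effect under IL-1β at 72 h depends on where the spread is taken from. With the 6 compared libraries limma called 0 genes (1418 at an unadjusted p under 0.05) against 1520 with all 24, so the spread between these libraries may account for the calls. The shift of the IL-1β-responsive genes did not hang on 1 library when the spread of 24 libraries was used: the median of the raised set nearest to 0 was -0.139, without replicate 1 of the IL-1β-treated normal cultures. With the 6 libraries and the replicate block the raised set had a fry adjusted p = 0.0689, and with the 6 libraries alone adjusted p = 0.0385, so a biological effect of the fibroblasts and a difference between individual cultures both stay open.

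The 6 libraries of each simple comparison were also divided in all 10 ways into 3 and 3, too few for a share under 0.05. Every division but the real one mixed the 2 groups, so a difference between them widened its spread and lowered its count. Low counts in the other divisions therefore do not measure chance. The real division and the highest other gave 8215 and 0 genes for IL-1β at 36 h and 7718 and 0 at 72 h in normal culture, 7145 and 0 and 5978 and 0 in co-culture, 1885 and 0 for co-culture without IL-1β at 36 h and 414 and 1 at 72 h, 1285 and 5 for co-culture under IL-1β at 36 h, and 7112 and 0 for 72 h against 36 h. In each of these 1 of the 10 divisions, the real one, gave as many genes. For co-culture under IL-1β at 72 h 2 of the 10 did: 1520 for the real division and 2307 for replicates 1 and 2 of the normal cultures with replicate 1 of the co-cultures against the other 3. Of the remaining 5 divisions that keep 2 same-numbered pairs together, limma called 1293, 981, 1, 0 and 0 genes, and the 3 others that part all same-numbered pairs called 0. The mixed divisions with 2307, 1293 and 981 genes all kept replicate 3 of both cultures on 1 side, as did the one with 1 gene. Mixed divisions that parted these 2 libraries called 0. Number 3 also had the highest correlation of deviations between the cultures (0.577). The samples therefore differ along more than the 2 groups. In these divisions the further difference went with replicate number 3, and its cause was not tested.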

How the results depend on the processing

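Weights per library, weights per group, the compared groups with the replicate block, list counts without single libraries and the medians of single lists under each scaling were chosen after the results were seen. The other alternatives, among them the number of lists passing under each scaling, were chosen before. Of 5449 values of named genes under an alternative, 5202 kept their direction and their side of the threshold, 196 lost and 36 gained a call in the same direction, and 15, none of them called, changed direction.

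With the compared groups only, co-culture without IL-1β called 3095 genes at 36 h and 1330 at 72 h, co-culture under IL-1β at 72 h called 0 by limma (1418 at an unadjusted p under 0.05), the interaction 1793 at 36 h and 12 at 72 h, and the difference between times of the co-culture effect 83. The spread then came from the compared libraries alone, which is less than that of all 24 without IL-1β and more at 72 h with it. With the replicate block added to these 6 libraries, co-culture under IL-1β at 72 h again called 0 (2752 unadjusted). Weights per library, which did not converge, gave 3667, 2084, 2456 and 2287 for co-culture without and under IL-1β at 36 h and 72 h, 2239 and 1420 for the interactions and 1035 for the difference between times. Weights per group, added for that reason, gave 3514, 1781, 2075 and 78, 1957 and 65, and 106. A replicate block within time gave 680 for co-culture without IL-1β at 72 h and 632 for the interaction at 72 h, and the cause was not tested. Every count of the IL-1β effects and of 72 h against 36 h stayed within 1.5 times under all of these, and no count moved by more under either pseudocount, filter or scaling.

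Lists past the threshold with an estimated correlation numbered 5 and 5 for IL-1β in normal culture at 36 h and 72 h (12 and 18 at the preset one), 5 and 6 in co-culture (13 and 18), 1 and 0 for co-culture without IL-1β (7 and 8), 0 and 3 under it (15 and 14), 1 and 2 for the interactions (8 and 11), 2 and 0 for the differences between times (13 and 10) and 7 for 72 h against 36 h (22). With fry they were 23 and 28, 25 and 28, 5 for co-culture without IL-1β at 72 h, 3 for the interaction at 72 h, and 23 and 6 for the differences between times. Rescaled to TPM, 4 lists passed for co-culture without IL-1β at 36 h, and the set raised by IL-1β at 36 h had a median of -0.11 in the interaction at 72 h, past the threshold no longer. The cause was not tested.

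The 15 changed directions were small. After TPM rescaling Adamts5 with IL-1β at 36 h was -0.00195, and without IL-1β at 72 h Col2a1 was -0.0152 and Ptgs2 -0.0338 in co-culture (-0.0352 with weights per library). Leaving out 1 library, Col2a1 ran from -0.00313 to 0.0632 and Ptgs2 from -0.0927 to 0.0607 there, and Il6 from -0.162 to 0.0129 under IL-1β at 36 h. Under IL-1β at 72 h Mmp3 ran from -0.280 to 0.0246, Mmp13 from -0.360 to 0.00448, Acan from -0.0649 to 0.284, Col2a1 from -0.00260 to 0.0941 and Adamts4 from -0.0826 to 0.0148.

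Without 1 library, counts ran from 7713 to 7843 and 7164 to 7620 for IL-1β in normal culture, 6477 to 6579 and 5264 to 5741 in co-culture, 4976 to 6328 for their difference between times in normal culture, 6386 to 6635 for 72 h against 36 h and 623 to 770 for the interaction at 36 h. Co-culture without IL-1β gave 1255 (without replicate 1 of normal culture) to 1422 at 36 h, and at 72 h 184, 201 and 168 without replicates 1, 2 and 3 of normal culture and 174, 221 and 153 without those of co-culture. Under IL-1β at 36 h the range was 738 (without replicate 1 of normal culture) to 994, with 831, 835 and 771 without the co-cultures in turn. At 72 h it was 613 and 2461 without replicates 1 and 3 of normal culture and 889 and 593 without replicates 1 and 2 of co-culture. The interaction at 72 h gave 203, 170 and 191 without the untreated normal cultures, 583 and 1167 without replicates 1 and 2 of the treated ones, 184 and 115 without replicates 2 and 3 of the untreated co-cultures, and 107, 115 and 997 without the treated ones. The difference between times of the co-culture effect gave 196 and 167 without replicate 1 of the treated normal and co-cultures at 36 h, and at 72 h 550 and 571 without replicates 1 and 2 of the treated normal and 206 and 203 without those of the treated co-cultures. Depth, which is unknown, limits what can be said of genes near 0 FPKM.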

Other observations

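Lists of further processes were measured but belong to none of the main results. Between 36 h and 72 h in untreated normal culture, interferon response genes fell in 17 of 23 cases (median -0.67, camera adjusted p = 1.22e-05, adjusted p = 0.268 with an estimated correlation), MHC class I genes in 11 of 13 (median -0.74, camera adjusted p = 1.22e-05, adjusted p = 0.132 with an estimated correlation), fibrillar and fibroblast matrix genes in 19 of 29 (median -0.27, camera adjusted p = 1.82e-06, adjusted p = 0.0709 with an estimated correlation) and WNT pathway genes in 13 of 19 (median -0.62, camera adjusted p = 8.33e-05, adjusted p = 0.0403 with an estimated correlation), while cholesterol synthesis genes rose in 21 of 23 (median 0.36, camera adjusted p = 1.22e-05, adjusted p = 0.115 with an estimated correlation). IL-1 receptor pathway genes fell in 7 of 12 cases and rose in 3 (median -0.30, camera adjusted p = 0.013, adjusted p = 0.167 with an estimated correlation), and growth factor and IGF binding protein genes fell in 13 of 26 and rose in 6 (median -0.23, adjusted p = 0.00524, adjusted p = 0.167 with an estimated correlation). With IL-1β at 72 h in normal culture, MHC class I genes rose in 9 of 13 cases (median 0.30, camera adjusted p = 0.00384, adjusted p = 0.289 with an estimated correlation), protease inhibitor genes in 8 of 13 (median 0.75, camera adjusted p = 0.0363, adjusted p = 0.289 with an estimated correlation), and growth factor genes in 14 of 26 with 10 lower (median 0.61, camera adjusted p = 0.00816, adjusted p = 0.256 with an estimated correlation). Under IL-1β at 72 h, growth factor genes were lower in co-culture in 8 of 26 cases (median -0.18, camera adjusted p = 8.21e-05, adjusted p = 0.128 with an estimated correlation) and protease inhibitor genes in 6 of 13 (median -0.26, camera adjusted p = 0.00138, adjusted p = 0.174 with an estimated correlation), with the spread of all 24 libraries; none of them passed with the 6 compared libraries alone, where limma called 0 of all genes and 1418 at an unadjusted p under 0.05.

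Of 32 tested lists 20 did not pass for IL-1β at 36 h in normal culture. Among them were the chondrocyte transcription factors and signals (4 higher and 8 lower of 12, median -0.66, camera adjusted p = 0.264) and the markers of other cell types. These were osteoclasts (median -0.31, adjusted p = 0.273, 3 tested), osteoblasts and osteocytes (0.41, adjusted p = 0.442, 5 tested), endothelial and mural cells (0.21, adjusted p = 0.752, 5 tested), adipocytes (-0.36, adjusted p = 0.273, 6 tested) and keratinocytes (-0.21, adjusted p = 0.814, 3 tested). The other 14 were hypoxia and glycolysis, complement, growth factors, WNT pathway, synovial lining, skeletal muscle, protease inhibitors, IL-1 receptor pathway, dermal fibroblast markers, interferon response, macrophage and leukocyte markers, fibrillar and fibroblast matrix, cholesterol synthesis, and hypertrophy and mineralization (camera adjusted p from 0.16 to 0.843). None of the 5 cell type lists named with values passed in the 4 co-culture comparisons. Mitochondrially encoded genes, 13 in number, were missing from the table and could not be tested.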
